A study of Synechocystis sp. PCC 6803 with 24 samples.

How the data were processed

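The study compared 4 RNA pools of Synechocystis sp. PCC 6803, a unicellular cyanobacterium: wild type and a partially disrupted slr0643 mutant, each at either of pH 6.5 and pH 7.5. Per the labels, cells were grown at 30 °C in BG11 medium with 20 mM HEPES at a light of 30 µmol per square metre and second, kanamycin at 40 µg per mL was added for the mutant alone, and cells were collected and resuspended in fresh medium at either pH. How long they stayed there is not given in the sources used here. The series design states that RNA of 3 experiments was pooled and that chips and printings are technical repeats.

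Per the file headers, each deposited workbook of a chip gives for every spot the Cy3 and Cy5 signal intensity as the mean over the spot minus the mean local background, a validity flag per channel that compares the spot with its background, and the ratio of the channels. Per the file headers, the authors replaced signals under 10 by 10 and took a log2 ratio after a global lowess in the method the workbook calls G. The scanner and its software are not given in the sources used here. The sheets with uncorrected signals were used on 11 of the 12 chips, and those of chip 3 of the mutant against the wild type at pH 6.5 were not used here. The 2 samples of a chip hold the same workbook, so the 12 distinct workbooks were read and the printings told apart by the block of the spot. The deposited log2 values of the series matrix were set against the workbooks: in each of its 24 columns between 99.4 and 99.5% of the values equalled the method G log2 ratio of 1 printing within 1e-05, turned so that mutant over wild type or pH 6.5 over pH 7.5 is positive, and 16 columns carried the values of another chip of the same comparison than the one their sample names. Column medians lay between -0.172 and 0.175, and neither scale, centring nor direction remained unknown. No column of per-sample values was left unused for want of a sample.

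Each chip held 6344 spots, of which 6184 belonged to 3076 genes and 160 to 10 control names. Of the genes 3074 had 2 spots, 1 in each printing, and 2 had 18 spots. Gene names, symbols and products are those of the array annotation and can be old; symbols known from the fixed gene lists were used where the annotation gave another name for the list. The supplied reference uses other locus tags and was not used here, so no coordinates are given. Background-subtracted intensities were corrected once more with normexp at an offset of 50, which leaves no value at or below 0 (between 3 and 37 spots per chip were so), and normalised within each chip by loess with control spots at weight 0. Spots marked as dim were kept, and at most 2 spots per channel and chip were saturated on the 11 chips whose uncorrected signals were used. Chip 3 of the mutant against the wild type at pH 6.5, which had the highest median Cy3 signal, was not checked for saturation. Spots of a gene were averaged within a printing and the printings averaged. Across genes the printings of a chip correlated with r between 0.660 and 0.936 and differed by a median between -0.358 and 0.202. Swapped chips were turned to the common direction.

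Chips of 1 comparison are arrays of the same 2 pools, so they were averaged to 1 ratio before the fit. A loop model with 3 coefficients was fitted to the 4 ratios, weighted by their number of chips, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 1 residual degree of freedom per gene; the prior added 9.76 at a standard deviation of 0.108. The SE of every fitted ratio comes from this model. The tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each of the 5 contrasts, and genes were called at an adjusted p below 0.05. Shifts of 27 gene lists were tested with cameraPR at a preset correlation of 0.01 and adjusted over all 135 tests. The p-values quoted with an estimated correlation come from camera on single chips with a dye term. They differ from the first in the unit and the fit as well as in the correlation. A call lost there is therefore not evidence by itself that members vary together. For the iron list the estimated correlation was -0.048, below the preset one, and its call at pH 7.5 was still lost. The lists were the site-2 protease homologues, sigma factors, genes reported earlier as acid-induced, photosystem I, photosystem II, phycobilisome, ATP synthase, cytochrome b6f and soluble electron carriers, NDH-1 complex, inducible inorganic carbon uptake, carboxysome and Rubisco, nitrogen uptake and assimilation, phosphate regulon, iron uptake and iron stress, chaperones and Clp proteases, HtrA/Deg and FtsH proteases, oxidative stress defence, photoprotection, ribosomal proteins, sodium/proton antiporters and proton exchange, potassium uptake, bidirectional hydrogenase, type IV pili and motility, fatty acid desaturases, chlorophyll, haem and bilin synthesis, compatible solute synthesis and uptake and outer membrane porin-like proteins. Some genes belong to more than 1 list, and shifts of lists that share members are not separate results. Photoprotection holds the nblA and flavodiiron genes, and it shares hliA and hliB with the acid-induced genes. The acid-induced genes also share a member with the site-2 protease homologues and another with the sigma factors. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except for a loess of each printing separately and a list test with the replicate block, which were chosen after seeing the data.

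Genes named per comparison were the site-2 protease homologues, the 10 called genes with the largest rise and the 10 with the largest fall among those with the same sign on every chip (5 each way for the difference, with the same sign in both direct estimates), and up to 2 called members each way per list. Values of such genes in another comparison were given beside them, ssl0453 at pH 6.5 among them, and other names are said to be chosen after their values were seen. No linear fold is given for a transcript above background on 6 or fewer of 8 spots, or 3 or fewer of 4, in either pool. Its log2 ratio is then given, or, for a transcript dim on nearly all spots of both pools, the test alone.

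Each strain chip holds 2 replicate numbers of the labels, and the chips were numbered 1 to 4 in that order. That chips of the same number at either pH belong together is an assumption. Their deviations correlated across genes with r = 0.51, 0.74, 0.58 and 0.69 for numbers 1 to 4. Chips 2 to 4 matched best with their own number, while chip 1 matched best with number 2. Numbers also follow the dye orientation, and within an orientation, where 2 chips give only 1 value, r was 0.43 and 0.29. A fit with the number as a block was run for the difference of the acid response, where it can be made. Deviations that both strain comparisons share cancel in the misclosure of the loop. The SE and the calls of the mutant against the wild type at either pH therefore do not count them. Scan dates were not used here.

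The scripts were tested on simulated data of 3076 genes with known changes. The averaged fit recovered 100% of changes of 1 on the log2 scale in every comparison, and of the smaller changes simulated it recovered, for the mutant against the wild type, 100% at pH 7.5 and 99.5% at pH 6.5, 95% and 97.9% for the acid response of the wild type and the mutant, and 96% for the difference. False calls made up 3.38, 2.33, 4.41, 5.32 and 3.45% of calls in the same order. For the acid response of the mutant, a simulated shift of the phycobilisome list by 0.3 was called in 20 of 20 draws, with calls in 3 of 520 tests of other lists. The simulated noise was drawn independently for each gene and chip, whereas the estimated correlation of the phycobilisome list in the data was 0.136. Same-numbered strain chips also deviated together in the data. Between 200 and 379 genes were changed per comparison, fewer than were called in the data. These rates therefore do not cover lists whose members vary together, nor gene calls on chips that share deviations.

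Alternatives were single chips as the unit with and without a dye term, no loop, the chips of a comparison alone, no background correction, plain subtraction, global median centring, the series matrix, a filter on dim genes, either printing alone, a 2-fold minimum, equal weights, an intensity trend in the prior, each chip left out in turn, the replicate block, and for lists an estimated correlation and fry. The filter kept the 2180 genes above background in both channels on every chip used.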

Results

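Transcript levels were compared between wild type cells of the cyanobacterium Synechocystis sp. PCC 6803 and a mutant in which slr0643, a gene for a homologue of site-2 proteases (membrane proteases that cut their substrates within the bilayer), was partially disrupted. Both strains were resuspended in fresh medium at pH 7.5 or at pH 6.5, and the 4 RNA pools were hybridised in pairs to 2-colour arrays that closed a loop. The mutant was set against the wild type at pH 7.5 on 4 chips and at pH 6.5 on 4 chips, and pH 6.5 was set against pH 7.5 on 2 chips in the wild type and on 2 chips in the mutant. Each chip carried 2 printings of the gene set and each printing was deposited as 1 sample, which gave 24 samples from 12 chips. The dyes were swapped on 1 in every 2 chips of each comparison. Per the series design, RNA from 3 independent experiments was pooled before hybridisation and the chips and printings are technical repeats. Thus 1 pool stood for each strain and pH. The chips of a comparison were therefore averaged to 1 ratio before the fit. A gene's p-value from that fit measures the error of arrays made from the same 4 pools, not the spread between cultures. That error is taken from how far the averaged ratios miss closing the loop. A deviation shared by the 2 strain comparisons cancels there, as does one shared by the 2 acid comparisons. The p-values and SE of those comparisons do not count it. The SD over the chips of a comparison does not enter these gene p-values or the SE of a fitted ratio. The p-value of a list compares its members' t values with those of other genes. It measures neither array error nor the spread between cultures.

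The arrays measured 3076 genes. The median background-corrected signal of gene spots lay between 557 and 1098 units in the Cy3 channel and between 396 and 1111 units in the Cy5 channel over the 12 chips. Between 63.5 and 94.6% of gene spots passed the authors' validity flag in Cy5 and between 87.0 and 97.1% in Cy3, and the number of chips limits the precision of every ratio. Across genes, ratios of chips of the same dye orientation correlated with r between 0.87 and 0.89 for the mutant against the wild type at pH 7.5 and between 0.80 and 0.92 at pH 6.5. Chips of opposite orientation, after their sign was turned, correlated with r between 0.52 and 0.67 at pH 7.5, between 0.57 and 0.64 at pH 6.5, at 0.25 for the acid response of the wild type and at 0.42 for that of the mutant. Genes are not independent replicates, and these values describe the arrays only.

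The first comparison was a check on the strain itself. The slr0643 transcript was 2.24-fold lower in the mutant at pH 7.5 (log2 ratio -1.16 ± 0.05, SE; SD over 4 chips 0.20) and 2.37-fold lower at pH 6.5 (log2 ratio -1.24 ± 0.05, SE; SD over 4 chips 0.20). It was lower on all 4 chips at each pH, with limma adjusted p = 8.33e-09 and 8.81e-09. Where in the gene the spotted probe lies is not given in the sources used here. Another site-2 protease homologue, sll0528, went the opposite way and rose 5.3-fold in the mutant at pH 7.5 and 4.49-fold at pH 6.5. Of the other homologues, sll0862 fell at pH 7.5 (log2 ratio -0.30, lower on 3 of 4 chips) and at pH 6.5 (-0.46). The slr1821 transcript did not pass the test at pH 7.5 (0.06) and fell at pH 6.5 (-0.39). In the wild type at lower pH, slr0643 passed the test at 0.18 (adjusted p = 0.0495, with 0.25 and 0.02 on the 2 chips), a call that ended under 22 of 26 alternatives. There sll0528 (-0.01), sll0862 (0.15) and slr1821 (0.08) did not. In the mutant sll0528 (-0.25, a call lost under 7 of 26 alternatives) and slr1821 (-0.36, lost under 2 of 26 alternatives) fell at pH 6.5, and slr0643 (0.10) and sll0862 (-0.01) did not pass. The acid response of slr1821 (-0.44) and sll0528 (-0.24, a call lost under 6 of 26 alternatives) was lower in the mutant than in the wild type, and that of slr0643 (-0.08) and sll0862 (-0.16, a call gained under 6 of 26 alternatives) was not distinguished. As a list, the homologues did not shift in any comparison (adjusted p between 0.191 and 0.962), and their median and mean had opposite signs at pH 7.5 (-0.12 and 0.25) and at pH 6.5 (-0.42 and 0.02). Of these 4 genes 3 at pH 7.5 and 4 at pH 6.5 were called adjusted over the list alone, against 3 and 4 over all genes. The share of all genes on the array that was called was 64.5% at pH 7.5 and 60.4% at pH 6.5.

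**Figure D1:**
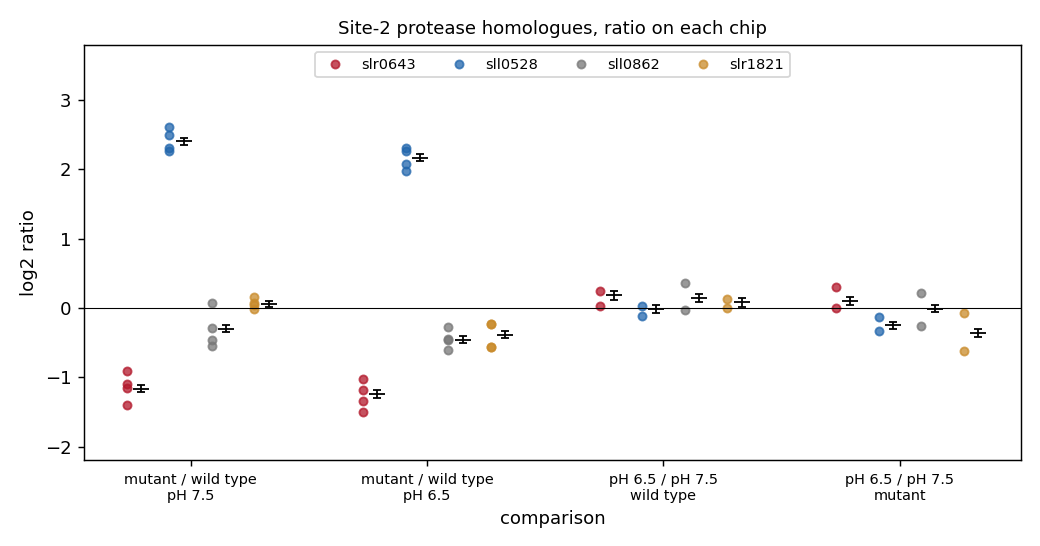
Log2 ratio of the 4 site-2 protease homologues (vertical axis) in the 4 comparisons (horizontal axis). Coloured points are single chips, and black bars are the fitted ratio ± SE; slr0643 lay below 0 and sll0528 above 0 on all 8 chips that set the mutant against the wild type.

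At pH 7.5, 7 of 8 genes reported earlier as acid-induced were higher in the mutant and 39 of 44 ribosomal protein genes were lower (adjusted p = 1.29e-15 and 4.07e-13 for the lists), and both shifts also passed with an estimated correlation. The gene of the serine protease HtrA (slr1204) was higher in the mutant by a log2 ratio of 2.75 ± 0.05 (SE; SD over 4 chips 0.13), with 5 of 8 spots above background in the wild type. The hspA gene (sll1514), which encodes a small heat shock protein, was 4.77-fold higher (2.25 ± 0.05; SD 0.20). The sll1236 transcript was higher by 3.06 (± 0.05; SD 0.18), with 6 of 8 spots above background in the wild type. The gene annotated as long-chain-fatty-acid CoA ligase (slr1609) rose 7.18-fold. The fhuA gene (sll1406), annotated as ferrichrome-iron receptor, was lower, with a log2 ratio of -1.81 ± 0.06 (SD 0.38) that stood at -0.82 without background correction. It was above background on 6 of 8 spots in the mutant and on all 8 in the wild type. Further rises came from sll1620 (2.76), ssr2194 (2.53), sll0528 (2.41), slr1687 (2.28), perR (slr1738, 2.27), a repressor of peroxide-inducible genes, and slr1206 (2.05). Further falls were those of the ribosomal genes rpl12 (sll1746, -1.62), rpl10 (sll1745, -1.50) and rpl1 (sll1744, -1.33). The photosystem I gene psaM (smr0005, -1.34) also fell, as did the sigma factor gene sigH (sll0856, -1.34) with its numerical neighbour sll0857 (-1.30), pcrR (sll1408, -1.30) and slr1484 (-1.21). In the mutant psaM was above background on 4 of 8 spots and pcrR on 3 of 8. Without background correction the ratio moved by over 1.5 times in fold, toward 0, for sll1236 (1.94), htrA (1.69), sll1620 (2.02), ssr2194 (1.39), slr1687 (1.57), slr1206 (1.36), psaM (-0.60) and pcrR (-0.44). The transcript of sll1407 was not well above background in the mutant on any of 8 spots and was so on 1 of 8 in the wild type. It passed the test as lower (limma adjusted p = 1.74e-08), but no fold is given, since nearly all of its spots lay near background in both strains.

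By gene list, 7 of 8 genes reported earlier as acid-induced were higher in the mutant at pH 7.5 (adjusted p = 1.29e-15), with hliA (ssl2542) 2.82-fold higher (log2 ratio 0.77 without background correction). Lists that are given as shifted with a single adjusted p also passed with an estimated correlation. In the list of HtrA/Deg and FtsH proteases 6 of 7 members rose (adjusted p = 7.21e-06, and adjusted p = 0.194 with an estimated correlation), hhoA (sll1679) by 0.64. In oxidative stress defence 8 of 10 rose and 1 fell (adjusted p = 0.00219, and adjusted p = 0.26 with an estimated correlation), with the peroxiredoxin gene sll1621 at 1.04 and the thioredoxin gene trxA (slr0623) at -0.46. In photoprotection 10 of 13 rose and 3 fell (adjusted p = 6.79e-04, and adjusted p = 0.286 with an estimated correlation), and sll0218 stood at 1.28 (0.49 without background correction, with 3 of 8 spots above background in the wild type). Chaperone and Clp protease genes passed the list test as higher (adjusted p = 0.0452, and adjusted p = 0.676 with an estimated correlation) although their median was -0.0026 and their mean 0.25. Of these genes 8 rose, among them dnaJ (slr0093, 1.46), and 6 fell, among them groEL2 (sll0416, -0.58) and groES (slr2075, -0.42). Genes of inducible inorganic carbon uptake rose in 11 of 13 cases (adjusted p = 1.55e-04, and adjusted p = 0.12 with an estimated correlation), with ndhD3 (sll1733) at 1.15 and ndhF3 (sll1732) at 1.13. The NDH-1 complex, which holds both, rose in 12 of 22 (adjusted p = 0.0141, and adjusted p = 0.306 with an estimated correlation). Ribosomal protein genes fell in 39 of 44 cases, by a median of -0.46 (adjusted p = 4.07e-13). Iron genes fell in 9 of 14 (adjusted p = 3.97e-04, and adjusted p = 0.0689 with an estimated correlation), with the iron-binding protein gene futA2 (slr0513) at -1.16. By contrast, feoB (slr1392), for ferrous iron uptake, rose by 0.81, with 0.48 on chip 1 and between 0.96 and 1.00 on the other chips. Photosystem I genes fell in 7 of 12 (adjusted p = 0.0168, and adjusted p = 0.132 with an estimated correlation). Photosystem II genes fell in 15 of 24 (adjusted p = 0.0176, and adjusted p = 0.373 with an estimated correlation). Genes of type IV pili and motility fell in 10 of 17 (adjusted p = 0.0143, and adjusted p = 0.132 with an estimated correlation). Among the sigma factors, sigB (sll0306, 1.01) and sigD (sll2012, 0.96) rose while sigF (slr1564, -0.64) and sigH fell, without a shift of the list (adjusted p = 0.701). Adjusted over the list alone, with the count over all genes in parentheses, the members called in either direction numbered 8 (7) for the acid-induced genes, 6 (6) for the HtrA/Deg and FtsH proteases, 9 (9) for oxidative stress defence, 13 (13) for photoprotection, 14 (14) for chaperones and Clp proteases and 12 (12) for carbon uptake. For the other lists named above they numbered 16 (16) for the NDH-1 complex, 41 (40) for ribosomal proteins, 12 (12) for iron uptake, 9 (8) for photosystem I, 16 (16) for photosystem II and 11 (11) for pili and motility. Of all genes on the array 64.5% were called in this comparison, so a count near that share is no trait of a list.

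In all, 1984 of 3076 genes passed limma's moderated test on the averaged ratios in the loop model at an adjusted p below 0.05, 999 higher and 985 lower in the mutant. Of these 53 were at least 2-fold higher and 21 at least 2-fold lower. Only 1363 of the 1984 had the same sign on every chip of this comparison. The smallest called change was 0.12 and the median SE 0.05. The count was 1110 when single chips were fitted without a dye term, and 1274 without chip 2 of the acid response of the wild type.

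At pH 6.5, all 12 photosystem I genes, 13 of 15 phycobilisome genes and 18 of 21 genes of chlorophyll, haem and bilin synthesis were lower in the mutant, and 7 of 8 genes reported earlier as acid-induced were higher. The shifts of these 4 lists also passed with an estimated correlation (adjusted p between 1.27e-23 and 4.85e-08 with the preset one). Both nblA genes, whose products trigger phycobilisome degradation, were higher in the mutant, ssl0452 by 4.7-fold (log2 ratio 2.23 ± 0.05, SE; SD over 4 chips 0.22) and ssl0453 by 4.22-fold (2.08 ± 0.05; SD 0.14). The phycobilisome linker gene cpcG (sll1471) was lower (-1.77 ± 0.06; SD 0.23), with 6 of 8 spots above background in the mutant. The photosystem I gene psaC (ssl0563) was 3.27-fold lower (-1.71 ± 0.06; SD 0.31). Further rises were those of slr1609 (3.05), fabG (sll0330, 2.71), annotated as 3-ketoacyl-acyl carrier protein reductase, sll0218 (2.68) and sll1236 (2.65). Next came the flavodiiron protein gene flv2 (sll0219, 2.55), hspA (sll1514, 2.27), ssr2016 (2.21), slr1544 (2.18) and sll0528 (2.17). Transcripts that fell also included sigH (sll0856, -1.75) with sll0857 (-1.78) and sll0858 (-1.69). Falls were also those of psaM (smr0005, -1.64), psaL (slr1655, -1.46), chlB (slr0772, -1.38) of light-independent protochlorophyllide reductase, sll0563 (-1.35) and sll1306 (-1.35). The psaM transcript was above background on 2 of 8 spots in the mutant and ssr2016 on 4 of 8 in the wild type, and sll1306 stood at -1.52 on chip 2 and between -1.33 and -1.30 on the other chips. Without background correction the fold moved by over 1.5 times, toward 0, for sll0218 (1.85), sll1236 (1.44), cpcG (-1.10), hspA (1.57), psaM (-0.47), ssl0453 (1.43) and ssr2016 (0.85), and with the series matrix psaM stood at -2.28.

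All 12 photosystem I genes fell, by a median of -0.99 (adjusted p = 2.68e-12). Phycobilisome genes fell in 13 of 15 cases, by a median of -0.92 (adjusted p = 1.52e-14), with cpcD (ssl3093) at -1.28. The exceptions were cpcE (slr1878, 0.31) and cpcF (sll1051, 0.16), which encode a lyase that attaches the pigment and are not structural. The call of cpcF ended under 14 of 26 alternatives. Photosystem II genes fell in 21 of 24 (adjusted p = 4.37e-06, and adjusted p = 0.132 with an estimated correlation), with psbO (sll0427) at -1.04 and psbB (slr0906) at -0.88. All 10 genes of ATP synthase fell (adjusted p = 0.0339, and adjusted p = 0.0536 with an estimated correlation), with atpF (sll1324) at -0.48. Genes of chlorophyll, haem and bilin synthesis fell in 18 of 21 (adjusted p = 4.85e-08), with chlN (slr0750) at -1.06. Nitrogen genes fell in 11 of 20 (adjusted p = 0.00936, and adjusted p = 0.0984 with an estimated correlation), with narB (sll1454), for nitrate reductase, at -1.10 and the nitrate transport gene nrtA (sll1450) at -0.89. The gene gifB (sll1515), an inhibitor of glutamine synthetase, rose by 1.26. Photoprotection genes rose in 10 of 13, by a median of 1.79 (adjusted p = 1.62e-25, and adjusted p = 0.0835 with an estimated correlation). The exceptions were hliD (ssr1789, -0.46), slr1964 (-0.42) and the flavodiiron gene sll1521 (-0.27, lost under 2 of 26 alternatives), the last named after its value was seen. Acid-induced genes of earlier reports rose in 7 of 8 (adjusted p = 1.27e-23). This list shares hliA and hliB with photoprotection, which also holds the nblA and flavodiiron genes. Carbon uptake genes rose in 10 of 13 (adjusted p = 1.03e-07, and adjusted p = 0.066 with an estimated correlation), with the bicarbonate transporter gene sbtA (slr1512) at 1.14. NDH-1 genes rose in 13 of 22 (adjusted p = 9.38e-05, and adjusted p = 0.181 with an estimated correlation), with ndhD2 (slr1291) at 1.84. Chaperones and Clp proteases rose in 10 of 17 (adjusted p = 7.11e-05, and adjusted p = 0.261 with an estimated correlation). HtrA/Deg and FtsH proteases rose in 5 of 7 (adjusted p = 0.0168, and adjusted p = 0.357 with an estimated correlation), with htrA (slr1204) at 1.58 (0.99 without background correction). Oxidative stress genes rose in 6 of 10 (adjusted p = 0.0108, and adjusted p = 0.294 with an estimated correlation), with slr1738 at 1.72. Adjusted over the list alone, with the count over all genes in parentheses, the members called in either direction numbered 12 (12) for photosystem I, 15 (15) for phycobilisome, 23 (22) for photosystem II, 10 (10) for ATP synthase, 19 (19) for chlorophyll, haem and bilin synthesis, 14 (14) for nitrogen uptake and assimilation and 13 (13) for photoprotection. For the other lists named above they numbered 7 (7) for the acid-induced genes, 10 (10) for carbon uptake, 18 (18) for the NDH-1 complex, 12 (12) for chaperones and Clp proteases, 6 (6) for the HtrA/Deg and FtsH proteases and 9 (8) for oxidative stress defence. Of all genes on the array 60.4% were called in this comparison.

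Of 3076 genes, 1858 passed the limma test, 950 higher and 908 lower in the mutant at pH 6.5, with 52 at least 2-fold higher and 34 at least 2-fold lower. Only 1271 of the 1858 had the same sign on every chip of this comparison. The count was 1102 with single chips and no dye term, 1152 and 1121 without chip 1 and chip 2 of the acid response of the wild type, and 1226 without chip 2 of that of the mutant. Across all genes, the ratios of the mutant over the wild type taken directly from the pH 7.5 chips and from the pH 6.5 chips, which share no RNA pool, correlated with Pearson's r = 0.70 and Spearman's rho = 0.63. They had the same sign in 72.9% of genes. This is a description across genes, which are not independent replicates.

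**Figure D2:**
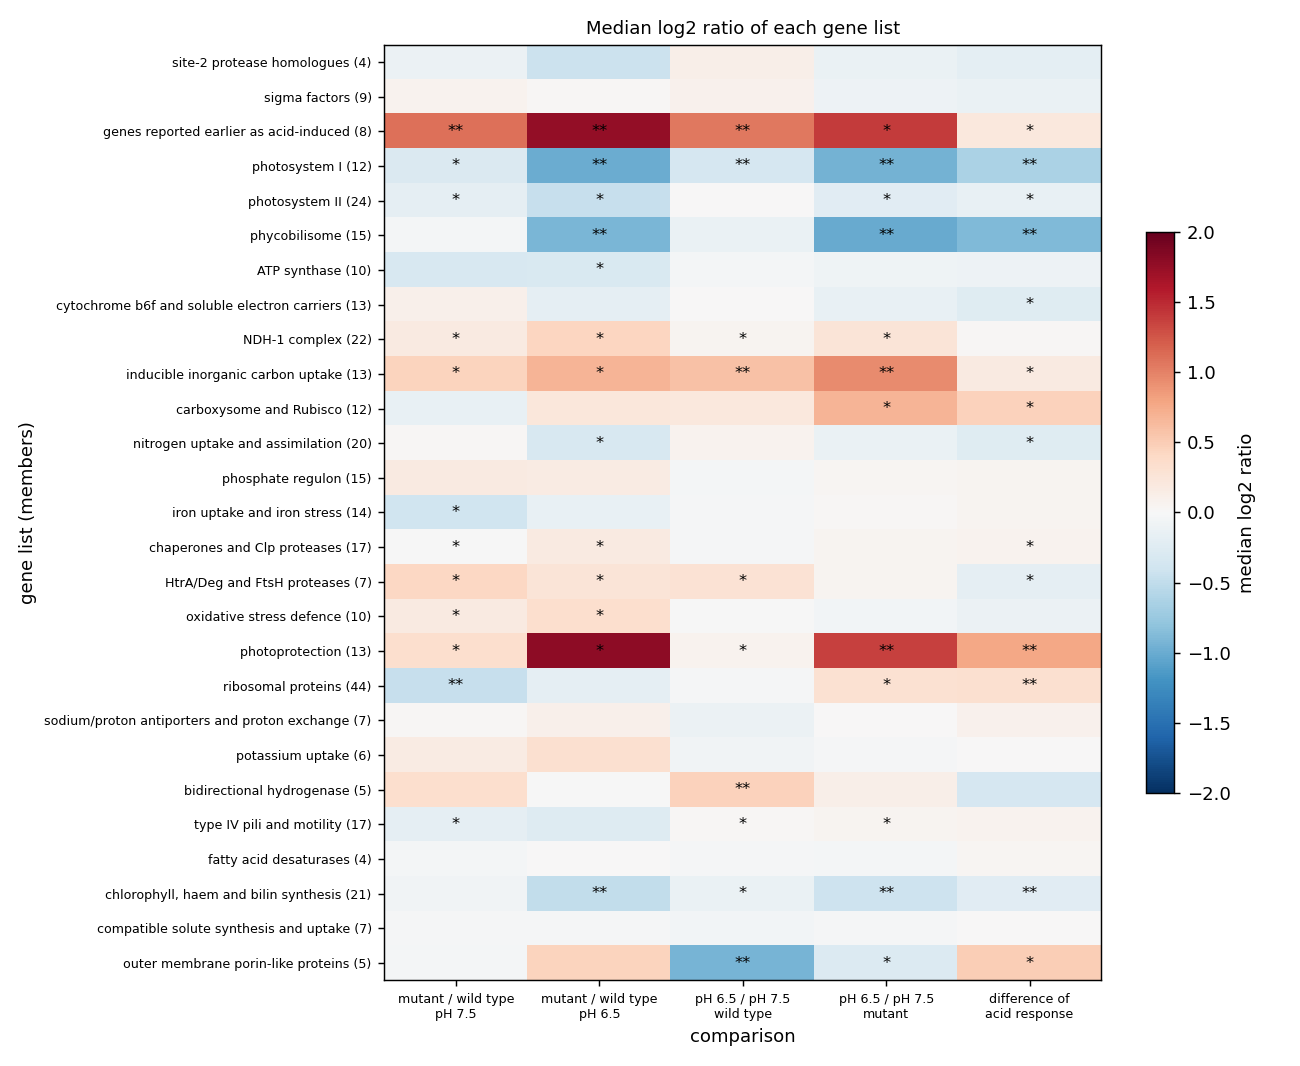
Median log2 ratio (colour) of the 27 gene lists (rows, with the number of members) in the 5 comparisons (columns). A star marks a shift at adjusted p below 0.05 with the preset correlation and a double star a shift that also passed with an estimated correlation; photosystem I passed in both ways at pH 6.5 in the mutant, with a median of -0.95.

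In the wild type at pH 6.5, 9 of 13 carbon uptake genes, all 5 hydrogenase genes and 6 of 8 genes reported earlier as acid-induced rose, and 3 of 5 porin-like and 10 of 12 photosystem I genes fell. The shifts of these 5 lists also passed with an estimated correlation (adjusted p between 6.12e-16 and 0.00245 with the preset one). The gene gspD (slr1277), which encodes the secretin of the pilus, fell 5.86-fold at pH 6.5 (log2 ratio -2.55 ± 0.06, SE; SD over 2 chips 0.14). The porin-like genes slr1908 and slr1841 fell 5.03-fold (-2.33 ± 0.07; SD 0.18) and 4.29-fold (-2.10 ± 0.06; SD 0.08). The ammonium transporter gene amt1 (sll0108) fell, with a log2 ratio of -2.03 ± 0.06 (SD 0.36) that stood at -0.85 without background correction, and was above background on 2 of 4 spots at pH 6.5. The slr1805 transcript, annotated as a histidine kinase, rose by 1.63 (± 0.08; SD 0.27), and so did the carbon uptake genes ndhD3 (sll1733, 1.48), cupA (sll1734, 1.40) and cupS (sll1735, 1.31). Further rises were those of sll0939 (1.38), slr0967 (1.30), flv2 (sll0219, 1.19), sll0382 (1.15), sll1483 (1.14) and the high light inducible protein gene hliB (ssr2595, 1.14). Further falls were those of slr2052 (-1.99), the sigma factor gene sigG (slr1545, -1.79), slr1501 (-1.76), slr0318 (-1.71), slr1113 (-1.55), annotated as an ABC transporter, and fhuA (sll1406, -1.45). Without background correction the fold moved by over 1.5 times, toward 0, also for fhuA (-0.64), hliB (0.51) and sll0382 (0.45).

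Of the 8 genes reported earlier as acid-induced, 6 rose and 1 fell (adjusted p = 5.21e-15). The gene that fell was sigB (sll0306, -0.25, a call lost under 8 of 26 alternatives), and sll0528 did not pass (-0.01). Carbon uptake genes rose in 9 of 13, by a median of 0.59 (adjusted p = 6.12e-16). All 5 genes of the bidirectional hydrogenase rose (adjusted p = 0.00245), with hoxU (sll1223) at 0.55 (a call lost under 3 of 26 alternatives). The NDH-1 genes rose in 8 of 22 (adjusted p = 0.00285, and adjusted p = 0.369 with an estimated correlation). HtrA/Deg and FtsH proteases rose in 5 of 7 (adjusted p = 6.66e-04, and adjusted p = 0.175 with an estimated correlation), with htrA (slr1204) at 1.05 and ftsH2 (slr0228) at 0.50 (lost under 2 of 26 alternatives). Photoprotection genes rose in 6 of 13 (adjusted p = 7.93e-04, and adjusted p = 0.433 with an estimated correlation). Of the 5 porin-like genes 3 fell (adjusted p = 8.52e-16). Genes of type IV pili and motility passed as lower (adjusted p = 9.11e-06, and adjusted p = 0.269 with an estimated correlation) with a median of 0.03 and a mean of -0.32. Of its 17 genes 7 fell, led by gspD and slr1275 (-1.09), and 3 rose. Photosystem I genes fell in 10 of 12, by a median of -0.33 (adjusted p = 9.23e-04), with psaC (ssl0563) at -0.65 (lost under 3 of 26 alternatives). Genes of chlorophyll, haem and bilin synthesis fell in 7 of 21 (adjusted p = 0.00879, and adjusted p = 0.0607 with an estimated correlation), with sll1874 at -1.07. Phycobilisome genes did not shift as a list (adjusted p = 0.233), although 7 of 15 fell. Neither did photosystem II (adjusted p = 0.887) or ribosomal proteins (adjusted p = 0.225). Adjusted over the list alone, with the count over all genes in parentheses, the members called in either direction numbered 7 (7) for the acid-induced genes, 10 (9) for carbon uptake, 5 (5) for the hydrogenase, 9 (9) for the NDH-1 complex and 5 (5) for the HtrA/Deg and FtsH proteases. For the other lists named above they numbered 10 (8) for photoprotection, 5 (3) for porin-like proteins, 12 (10) for pili and motility, 10 (10) for photosystem I and 10 (7) for chlorophyll, haem and bilin synthesis. Of all genes on the array 29.6% were called in this comparison.

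Over all genes, 912 of 3076 passed the limma test, 481 higher and 431 lower at pH 6.5 in the wild type, with 22 at least 2-fold higher and 22 at least 2-fold lower. Of the 912, 765 had the same sign on both chips. The count was 532 with single chips and a dye term, 292 without the loop, 48 from the 2 chips alone, 128 and 156 without chip 1 and chip 2 of this comparison, and 457 and 390 without chip 1 and chip 2 of the acid response of the mutant.

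In the mutant at pH 6.5, transcripts of light harvesting, photosystem I and chlorophyll synthesis fell, and those of photoprotection and carbon uptake rose. The flavodiiron gene flv2 (sll0219) rose by a log2 ratio of 2.82 ± 0.05 (SE; SD over 2 chips 0.13), with 3 of 4 spots above background at pH 7.5. The neighbouring sll0218 rose 5.57-fold (2.48 ± 0.06; SD 0.44). The agmatine ureohydrolase gene speB (sll1077) fell 3.9-fold (-1.97 ± 0.06; SD 0.27), and psaC (ssl0563) fell 3.64-fold (-1.87 ± 0.07; SD 0.04). Further rises were those of slr1544 (2.06), hliB (ssr2595, 2.06), sbtA (slr1512, 1.74), sll1483 (1.74), ndhD2 (slr1291, 1.71), nblA (ssl0452, 1.68), cupS (sll1735, 1.66) and the gene annotated as glutathione peroxidase (slr1992, 1.59). Further falls were those of slr2052 (-1.87), sll1080 (-1.80), sll1078 (-1.79), chlL (slr0749, -1.79) and chlN (slr0750, -1.70) of light-independent protochlorophyllide reductase, gspD (slr1277, -1.78), amt1 (sll0108, -1.62) and slr1841 (-1.62). At pH 6.5 the amt1 transcript was above background on 1 of 4 spots. Without background correction the fold moved by over 1.5 times, toward 0, for flv2 (2.15), sll0218 (1.68), hliB (1.06), cupS (1.05), sll1080 (-1.16), sll1078 (-0.88), chlN (-1.01) and amt1 (-0.56).

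All 12 photosystem I genes fell, by a median of -0.95 (adjusted p = 3.83e-15). Phycobilisome genes fell in 12 of 15 cases, by a median of -1.01 (adjusted p = 5.15e-19), with cpcC (sll1580) at -1.31 and apcB (slr1986) at -1.30. Chlorophyll, haem and bilin synthesis genes fell in 17 of 21 (adjusted p = 3.00e-12). Photosystem II genes fell in 14 of 24 (adjusted p = 0.0106, and adjusted p = 0.347 with an estimated correlation), and porin-like genes fell in 3 of 5 (adjusted p = 0.00156, and adjusted p = 0.24 with an estimated correlation). Pili and motility genes passed as lower (adjusted p = 0.0149, and adjusted p = 0.503 with an estimated correlation) with a median of 0.06 and a mean of -0.25, and of its 17 genes 8 fell and 6 rose. Photoprotection genes rose in 9 of 13, by a median of 1.37 (adjusted p = 2.23e-26). Carbon uptake genes rose in 10 of 13 (adjusted p = 6.12e-16), as did NDH-1 genes in 12 of 22 (adjusted p = 6.31e-05, and adjusted p = 0.194 with an estimated correlation). Carboxysome and Rubisco genes rose in 8 of 12 (adjusted p = 4.37e-06, and adjusted p = 0.181 with an estimated correlation), with rbcX (slr0011) at 1.10 and rbcS (slr0012) at 1.09. Ribosomal protein genes rose in 33 of 44 (adjusted p = 7.34e-06, and adjusted p = 0.0536 with an estimated correlation), with rpl3 (sll1799) at 0.76. Of the genes reported earlier as acid-induced 6 of 8 rose (adjusted p = 4.30e-18, and adjusted p = 0.0607 with an estimated correlation), and sll0528 and sigB (sll0306, -0.39, lost under 1 of 26 alternatives) fell. No call was made among the 15 genes of the phosphate regulon, where the largest value was 0.12 for phoU (slr0741). Adjusted over the list alone, with the count over all genes in parentheses, the members called in either direction numbered 12 (12) for photosystem I, 13 (12) for phycobilisome, 18 (18) for chlorophyll, haem and bilin synthesis, 16 (15) for photosystem II, 4 (4) for porin-like proteins and 15 (14) for pili and motility. For the other lists named above they numbered 11 (10) for photoprotection, 11 (11) for carbon uptake, 16 (16) for the NDH-1 complex, 10 (10) for carboxysome and Rubisco, 35 (35) for ribosomal proteins and 8 (8) for the acid-induced genes. Of all genes on the array 50.4% were called in this comparison.

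In the mutant, 1551 of 3076 genes passed the limma test, 769 higher and 782 lower at pH 6.5, with 32 at least 2-fold higher and 39 at least 2-fold lower. Of the 1551, 1195 had the same sign on both chips. The count was 971 with single chips and a dye term, 593 without the loop, 178 from its 2 chips alone, 566 and 575 without chip 1 and chip 2 of the acid response of the wild type, and 944 without chip 1 of this comparison. Across all genes, the acid responses of the strains taken directly from their own chips, which share no RNA pool, correlated with Pearson's r = 0.59 and Spearman's rho = 0.47. They had the same sign in 65.7% of genes.

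The loop allowed the acid responses of the strains to be compared in 1 test, which bears on the role of slr0643 in acid acclimation named in the series title. The nblA genes rose at pH 6.5 in the mutant (1.68 for ssl0452 and 1.38 for ssl0453). In the wild type ssl0452 did not pass (-0.15) and ssl0453 fell (-0.39, a call lost under 3 of 26 alternatives). The response of ssl0452 was higher in the mutant by a log2 ratio of 1.83 ± 0.06 (SE) and that of ssl0453 by 1.77 ± 0.06. The phycobilisome linker genes cpcG (sll1471, difference -1.41 ± 0.07) and apcE (slr0335, -1.15) had a lower response in the mutant. Of the genes of light-independent protochlorophyllide reductase, the response of chlL (slr0749, -1.71), chlN (slr0750, -1.48) and chlB (slr0772, -0.23, a call lost under 8 of 26 alternatives) was lower in the mutant. That of chlB did not pass with the replicate block (-0.22, adjusted p = 0.111). At pH 7.5 chlL (0.83) and chlN (0.42) stood higher in the mutant than in the wild type, and chlB (-1.15) stood lower. The nitrate transport gene nrtA (sll1450, -1.52) had a lower response in the mutant, as did sll1306 (-1.38). The nrtA transcript rose in the wild type (1.10) and fell in the mutant (-0.42, a call lost under 1 of 26 alternatives). By contrast, the flavodiiron genes flv2 (sll0219, 1.63) and flv4 (sll0217, 1.52) had a higher response, while the flavodiiron genes sll0550 (0.10) and sll1521 (-0.09) were not distinguished. The fhuA transcript (sll1406) passed the test as higher in response (1.71, or 0.75 without background correction). At pH 6.5 it was above background on 2 of 8 spots in the mutant and 5 of 8 in the wild type, so the size of this difference is uncertain. The wild type fell (-1.45) and the mutant rose by 0.27 (a call that ended under 10 of 25 alternatives), from a level lower than that of the wild type at pH 7.5. The htrA transcript (slr1204) rose in the wild type (1.05), and did not pass in the mutant (-0.12), where it was higher at both pH values. Its response differed by -1.17 ± 0.06. Without background correction the difference stood at -0.86 for chlN.

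Photosystem I genes had a lower response in the mutant in 8 of 12 cases (adjusted p = 6.80e-10), with psaA (slr1834) at -1.17. Phycobilisome genes had a lower response in 13 of 15 (adjusted p = 1.36e-21), and so had genes of chlorophyll, haem and bilin synthesis in 11 of 21 (adjusted p = 1.09e-08). The response was also lower in 12 of 24 photosystem II genes (adjusted p = 0.00318, and adjusted p = 0.305 with an estimated correlation). It was lower in 7 of 13 genes of cytochrome b6f and soluble electron carriers (adjusted p = 0.0401, and adjusted p = 0.403 with an estimated correlation), with petC (sll1316) at -0.83. It was lower in 12 of 20 nitrogen genes (adjusted p = 0.00217, and adjusted p = 0.0754 with an estimated correlation) and in 4 of 7 HtrA/Deg and FtsH protease genes (adjusted p = 0.0191, and adjusted p = 0.357 with an estimated correlation). Among the photoprotection genes, which include the nblA and flavodiiron genes named above, it was higher in 9 of 13 (adjusted p = 7.49e-22). It was higher in 31 of 44 ribosomal protein genes (adjusted p = 1.69e-12), with rpl12 (sll1746) at 1.11. It was higher in 8 of 12 carboxysome and Rubisco genes (adjusted p = 1.93e-04, and adjusted p = 0.2 with an estimated correlation), with rbcL (slr0009) at 0.70, and in 4 of 5 porin-like genes (adjusted p = 0.00135, and adjusted p = 0.132 with an estimated correlation), with slr1908 at 1.03. The same held for 7 of 13 carbon uptake genes (adjusted p = 0.0452, and adjusted p = 0.439 with an estimated correlation), with sbtB (slr1513) at 0.94. With the replicate number of the strain chips as a block, the shift of the carbon uptake genes did not pass (adjusted p = 0.0758). Chaperones and Clp proteases passed as higher (adjusted p = 0.0104, and adjusted p = 0.503 with an estimated correlation), 7 of 17 with a higher and 3 with a lower response, with groES (slr2075) at 1.12 and groEL1 (slr2076) at 0.94. The genes reported earlier as acid-induced had a higher response in 4 of 8 (adjusted p = 0.00285, and adjusted p = 0.294 with an estimated correlation), with slr1544 at 1.10. Adjusted over the list alone, with the count over all genes in parentheses, the members called in either direction numbered 9 (8) for photosystem I, 13 (13) for phycobilisome, 13 (13) for chlorophyll, haem and bilin synthesis, 13 (13) for photosystem II, 9 (8) for cytochrome b6f and carriers, 15 (15) for nitrogen uptake and assimilation and 4 (4) for the HtrA/Deg and FtsH proteases. For the other lists named above they numbered 9 (9) for photoprotection, 33 (32) for ribosomal proteins, 8 (8) for carboxysome and Rubisco, 4 (4) for porin-like proteins, 10 (9) for carbon uptake, 10 (10) for chaperones and Clp proteases and 5 (5) for the acid-induced genes. Of all genes on the array 41.3% were called for the difference.

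**Figure D3:**
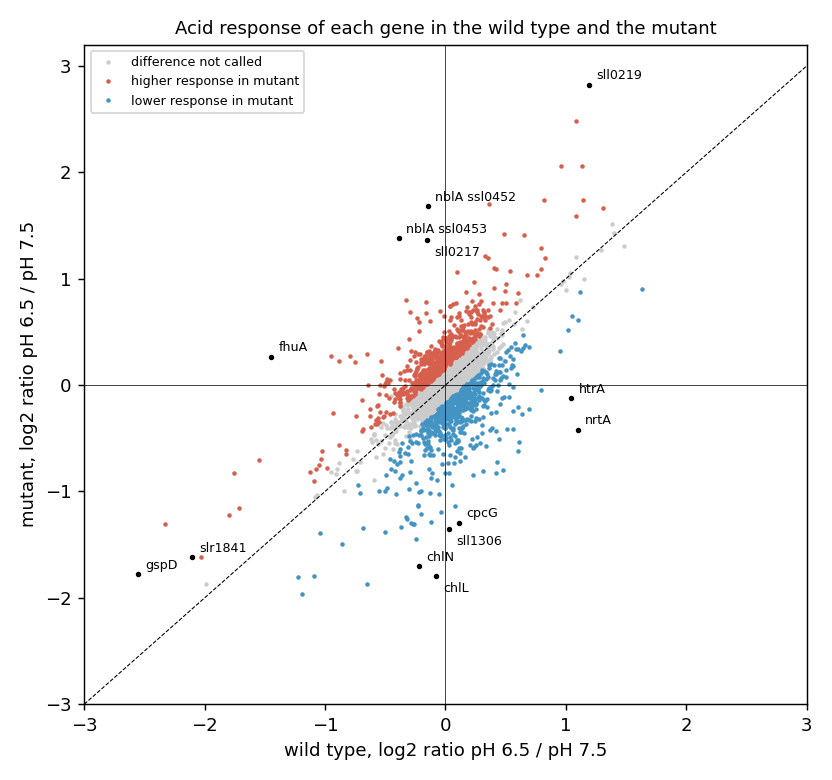
Log2 ratio of pH 6.5 over pH 7.5 in the wild type (horizontal axis) and in the mutant (vertical axis), 1 point per gene, with named genes in black and other genes coloured where the difference passed the test and the dashed line marking equal responses. The nblA genes, flv2 (sll0219) and flv4 (sll0217) sat above the line and chlL, chlN, cpcG and nrtA below it, with chlL at -0.08 in the wild type and -1.79 in the mutant.

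The difference passed the limma test in 1270 of 3076 genes, 635 with a higher and 635 with a lower response in the mutant, and was at least 2-fold in 35 genes. Its direct estimates from the strain chips and from the acid chips had the same sign in 1261 of the 1270. With the replicate number of the strain chips as a block the count was 770, with single chips and a dye term 801 and without the loop 524. It was 399 and 378 without chip 1 and chip 2 of the acid response of the wild type, and 597 and 671 without chip 1 and chip 2 of that of the mutant.

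The remaining lists, of the phosphate regulon, potassium uptake, sodium/proton antiporters, fatty acid desaturases and compatible solutes, did not shift in any comparison, and the same held for the sigma factors. In the mutant against the wild type, phosphate regulon genes rose in 10 of 15 cases at pH 7.5 (adjusted p = 0.215) and in 9 at pH 6.5 (adjusted p = 0.0964). The phosphate-binding protein gene pstS (sll0680) rose by 0.50 and 0.62. Potassium uptake genes rose in 3 and 4 of 6 (adjusted p = 0.354 and 0.305), with kdpA (slr1728) at 0.54 at pH 7.5. Sodium/proton antiporters rose in 2 and fell in 2 of 7 at pH 7.5 (adjusted p = 0.91). In the wild type at pH 6.5 1 rose and 2 fell (adjusted p = 0.749), among them slr1596 at 0.34 (a call lost under 5 of 25 alternatives, with 2 of 4 spots above background at pH 7.5). Among fatty acid desaturases, desC (sll0541) was higher in the mutant at both pH values (0.39 and 0.46) and the list was not (adjusted p = 0.904 and 0.977). Compatible solute genes stayed within a log2 ratio of -0.45 to 0.28 in the mutant against the wild type at pH 6.5 (adjusted p = 0.742). Adjusted over the list alone, with the count over all genes in parentheses, 10 (10), 3 (3), 4 (4), 1 (2), 1 (3) and 7 (7) members of these 6 lists, in the order named, were called at pH 7.5 in the mutant against the wild type. That comparison called 64.5% of all genes on the array.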

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

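Of the tests in this part, the comparison of the strain chips with the acid chips, the number of RNA pools and the search for wild type samples with kanamycin were chosen only after the result was seen.

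The acid response differed between the strains in 1270 genes, a test of the difference itself, with 8 of 12 photosystem I and 13 of 15 phycobilisome genes lower and the nblA genes, flv2 and flv4 higher in the mutant. Noise between chips is argued against by a correlation across genes, which are not independent replicates. The difference from the strain chips and that from the acid chips correlated with r = 0.859 (95% bootstrap interval 0.843 to 0.873). The differences from the 2 dye orientations of the strain chips correlated with r = 0.688 (0.658 to 0.712). A dye bias that was the same at both pH values cancels within each orientation, so that test could not show it. A bias that differed between the pH values would enter the 2 with opposite signs, and r = 0.688 argues against it as the main source. Of the 35 splits of the 8 strain chips into 4 and 4, 2 called as many genes as the split by pH (635), so chance is not excluded by that share, and the other was the split by dye orientation with 649. No other split called any gene in limma (0, with at most 407 at an unadjusted p below 0.05 against 1056 for the split by pH), the same held for the 7 others that part all 4 same-numbered pairs (at most 224), and with the pairing as a block the count was 770. Every split but that by pH leaves the pH difference at least in part in its residual, which lowers its calls. The chips of a pH repeat the same pools, so 635 against 0 does not decide on chance between pools. With 1 RNA pool per strain and pH, a difference between single pools cannot be told apart from one between the strains, so a part of slr0643 in the acid response may account for the pattern but was not tested, which would take further pools or a complemented strain.

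Of 8 genes reported earlier as acid-induced, 7 stood higher in the mutant at each pH, as did htrA (2.75 at pH 7.5 and 1.58 at pH 6.5) and hspA (2.25 and 2.27), while the lists of oxidative stress, chaperones and Clp proteases, and HtrA/Deg and FtsH proteases lost their calls with an estimated correlation at both (adjusted p between 0.194 and 0.676). Of these 8 genes, 6 rose at pH 6.5 in the wild type, while sll0528 (-0.01) did not pass and sigB (-0.25) fell. The sll0528 transcript had the highest ratio of the list in the mutant at pH 7.5 (2.41). A mutant that carries the wild type acid response at both pH values was tested by the correlation across genes of the mean mutant ratio with the wild type acid response, r = 0.235 (0.178 to 0.289; Spearman's rho 0.249), and the interval held the limit set for that explanation, so the test did not decide. Both wild type pools enter the mean ratio with a negative sign and the acid response with opposite signs, so the covariances that their deviations add cancel where they are of like size. Kanamycin was in the mutant's medium only and 0 wild type samples had it, so an effect of the antibiotic cannot be told apart from one of the mutation. Both explanations, and a response to the lowered slr0643 transcript, may hold.

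All 12 photosystem I and 12 of 15 phycobilisome genes fell at pH 6.5 in the mutant, and the median log2 ratio of these 27 genes was -1.01. A bias of bright spots is argued against, since 0 of 10000 random lists matched on mean signal had a median as low (the lowest was -0.22). Dye bias of single genes is argued against by a median of -0.85 on the chip with pH 6.5 in Cy3 and -0.95 on that with pH 6.5 in Cy5. Differences between single pools stay open, and so does an effect of the mutation, which was not tested apart from them. The phycobilisome list did not shift in the wild type (median -0.13, adjusted p = 0.233) and photosystem I had a median of -0.33.

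The strains also differed in their acid response, by a test of the difference, in the following genes, as log2 ratios of the mutant minus the wild type. Lower responses were those of chlL (slr0749, -1.71), nrtA (sll1450, -1.52), chlN (slr0750, -1.48), cpcG (sll1471, -1.41), sll1306 (-1.38), psaA (slr1834, -1.17), htrA (slr1204, -1.17), apcE (slr0335, -1.15), petC (sll1316, -0.83), chlB (slr0772, -0.23, a call lost under 8 of 26 alternatives), slr1821 (-0.44) and sll0528 (-0.24, a call lost under 6 of 26 alternatives). Higher responses were those of nblA (ssl0452, 1.83, and ssl0453, 1.77), flv2 (sll0219, 1.63), flv4 (sll0217, 1.52), groES (slr2075, 1.12), rpl12 (sll1746, 1.11), slr1544 (1.10), slr1908 (1.03), groEL1 (slr2076, 0.94), sbtB (slr1513, 0.94) and rbcL (slr0009, 0.70). For fhuA (sll1406) the difference passed the test (1.71, or 0.75 without background correction), but its size is uncertain, since 2 of 8 mutant and 5 of 8 wild type spots were above background at pH 6.5. Among genes chosen after their values were seen, the response was lower for sll1077 (-0.78), sll1078 (-0.70), sll1079 (-0.63), sll1080 (-0.58), sll1081 (-0.35), sll1082 (-0.66), slr0146 (-1.15), slr0147 (-1.22), slr0148 (-1.28), slr0149 (-1.25), slr0150 (-0.91), slr0151 (-0.82), cydA (slr1379, -1.16) and cydB (slr1380, -0.75). The call of sll1081 was lost under 6 of 26 alternatives, the replicate block among them, and that of sll1079 under 1.

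By list, the median difference was -0.64 for photosystem I, -0.15 for photosystem II, -0.89 for the phycobilisome, -0.23 for chlorophyll, haem and bilin synthesis, -0.24 for cytochrome b6f and carriers, -0.24 for nitrogen uptake and assimilation and -0.18 for HtrA/Deg and FtsH proteases. It was 0.77 for photoprotection, 0.32 for ribosomal proteins, 0.46 for carboxysome and Rubisco, 0.49 for porin-like proteins, 0.18 for carbon uptake, 0.22 for the genes reported earlier as acid-induced and 0.064 for chaperones and Clp proteases. With an estimated correlation the calls of photosystem I, the phycobilisome, chlorophyll, haem and bilin synthesis, photoprotection and ribosomal proteins held, and the other 9 were lost (adjusted p between 0.0754 and 0.503). That of carbon uptake was also lost with the replicate block (adjusted p = 0.0758).

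On 4 of 99 gene and comparison pairs with 4 chips, 1 chip stood far from the others by its gap over the range of the chips, and chance alone gives about 1 in 20. For slr1392 at pH 7.5 the share was 0.919, with 0.48 on chip 1 and 0.96 to 1.00 on the others. At pH 6.5 it was 0.869 for sll1306 (-1.52 on chip 2, -1.33 to -1.30 on the others), 0.885 for slr0644 (-0.10 on chip 3, 0.17 to 0.21 on the others) and 0.838 for slr1676 (1.24 on chip 2, 0.82 to 0.89 on the others).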

How the results depend on the processing

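A loess of each printing separately and the list tests with the replicate block were chosen after seeing the data; the other alternatives were planned. The fall of slr0643 in the mutant kept its direction and its call under all 26 alternatives at each pH, with a log2 ratio from -1.27 to -0.74 at pH 7.5 and from -1.31 to -0.84 at pH 6.5. Counts were within 1.5 times of the reported ones under every alternative not named here. With single chips and no dye term they were 1110 and 1102 for the pH 7.5 and the pH 6.5 comparison of the strains, 242 and 512 for the acid response of the wild type and the mutant, and 362 for its difference. A dye term gave 532 and 971 for the acid responses and 801 for the difference, and no loop gave 292, 593 and 524. The chips of a comparison alone gave 48 and 178 for the acid responses; these hold 2 chips each, and that fit also drops the loop, the averaging and the spread shared with other comparisons. Plain subtraction gave 580 for the wild type acid response, and the first printing alone 532 for it and 781 for the difference. For these settings the cause was not tested. A 2-fold minimum, which only removes calls, left 74, 86, 44, 71 and 35 in the order pH 7.5, pH 6.5, wild type, mutant and difference. With the pairing by replicate number as a block the difference was called in 770 genes, 748 of them among the 1270 and all 748 in the same direction, the shift of the carbon uptake list was lost (adjusted p = 0.0758) and so were sll1081 (-0.27, adjusted p = 0.112) and chlB (slr0772, -0.22, adjusted p = 0.111); the block changed no other call of a list or a named gene. The other comparisons set no groups that share numbers against each other.

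Leaving out 1 chip gave 1274 to 1972 called genes at pH 7.5, 1121 to 1815 at pH 6.5, 128 to 905 for the wild type acid response, 566 to 1551 for that of the mutant and 378 to 1240 for the difference. Without chip 1 or chip 2 of the wild type acid response, the 5 counts were 1342 and 1274, 1152 and 1121, 128 and 156, 566 and 575, and 399 and 378. Without chip 1 or chip 2 of that of the mutant they were 1378 and 1426, 1259 and 1226, 457 and 390, 944 and 1152, and 597 and 671. The remaining chip of such a comparison has 1 dye orientation, so a dye effect no longer cancels there. The strain chips have 4 per comparison, and leaving out any of them kept every count within 1.5 times.

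The gene lists gave 61 of 135 calls, and 21 with an estimated correlation on single chips, all among the 61. With fry on single chips 101 were called. That test asks whether a list's genes move one way and does not compare them with other genes. Of the 237 pairs of a named gene and a comparison, 199 kept their call under every alternative, 33 lost it under at least 1, 5 gained one (sll0862 in 6 for the difference, slr0643 in 1 for the mutant, slr1204 in 2 for the mutant, sll0862 in 3 for the wild type and ssl0452 in 2 for the wild type) and none turned its direction while called. The calls that ended, with the number of the 25 or 26 alternatives that ended them, were slr0643 (22), slr1380 (17), sll0306 (8), slr0151 (8), slr0150 (5), slr1596 (5), slr0146 (4), slr0148 (4), slr0149 (4), sll1223 (3), slr0147 (3), slr1379 (3), ssl0453 (3), ssl0563 (3), slr0228 (2), sll1079 (1) and sll1082 (1) for the wild type acid response; sll1406 (10), sll0528 (7), slr0146 (4), slr0147 (2), slr1380 (2), slr1821 (2), sll0306 (1), sll1450 (1), slr0150 (1) and slr0151 (1) for that of the mutant; slr0772 (8), sll0528 (6), sll1081 (6) and sll1079 (1) for the difference; and sll1051 (14) and sll1521 (2) for the mutant at pH 6.5. The alternative without background correction used 11 chips. Between the reported and the alternative values, the fold moved by over 1.5 times for 37 called pairs without background correction, all 37 toward 0 with the call kept, and for 2 of them (psaM at pH 6.5 and sll1407 at pH 7.5) with the series matrix, away from 0. Signal over background limits the dim genes: 2180 of 3076 were above it in both channels on every chip, and transcripts near it have ratios pulled toward 0 by the offset.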

Other observations

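The genes described here were chosen after their values were seen. The numbered neighbours sll1077 (speB, agmatine ureohydrolase) to sll1082 (annotated as nitrate transport protein NrtD), with sll1079 (hypB, a hydrogenase maturation protein) between them, fell together at pH 6.5 in both strains. In the wild type the log2 ratios were -1.19 for sll1077, -1.09 for sll1078, -0.86 for sll1079, -1.23 for sll1080, -1.04 for sll1081 and -0.69 for sll1082, and in the mutant -1.97, -1.79, -1.49, -1.80, -1.39 and -1.35 in the same order. The fall was larger in the mutant by a test of the difference for each of these genes, which for sll1081 did not pass with the replicate block (adjusted p = 0.112) and was lost under 6 of 26 alternatives in all. The call of sll1079 was lost under 1 for the difference and 1 in the wild type, and that of sll1082 in the wild type under 1 of 25. Without background correction the ratios in the mutant were -0.88 (sll1078), -1.16 (sll1080), -0.75 (sll1081) and -0.75 (sll1082). At pH 6.5 sll1082 was above background on 2 of 4 spots in the mutant. The genes slr0146 to slr0151, among them petF (slr0150), which encodes a ferredoxin, had a lower response in the mutant, a difference that kept its call under all 26 alternatives for each. In the wild type they rose by 0.61 (slr0146), 0.60 (slr0147), 0.48 (slr0148), 0.42 (slr0149), 0.34 (slr0150) and 0.25 (slr0151), and in the mutant the ratios were -0.54, -0.62, -0.80, -0.83, -0.57 and -0.57, all past the test. In the order of the genes, the calls in the wild type were lost under 4, 3, 4, 4, 5 and 8 of 26 alternatives and those in the mutant under 4, 2, 0, 0, 1 and 1. The genes of the quinol oxidase, cydA (slr1379) and cydB (slr1380), also had a lower response in the mutant under all 26. They stood at 0.43 and 0.26 in the wild type (calls lost under 3 and 17 of 26) and at -0.73 and -0.49 in the mutant (lost under 0 and 2).

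In the mutant against the wild type, hypA (slr1675), for a hydrogenase maturation protein, was higher at pH 7.5 (1.76) and at pH 6.5 (1.57), together with slr1676 (1.25 and 0.97), slr1677 (1.68, or 1.07 without background correction, and 0.76) and ssl3044, annotated as a hydrogenase component (1.61 and 1.47). The structural genes of the bidirectional hydrogenase did not shift as a list in this comparison (adjusted p = 0.203 at pH 7.5 and 0.98 at pH 6.5). At pH 7.5, however, 4 of the 5 were called higher, with log2 ratios of the list from 0.11 to 0.39, and at pH 6.5 1 of 5 was. Of the genes numbered next to slr0643, slr0642, annotated as an integral membrane protein, passed the test as higher in the mutant at both pH values, but no size is given, since it was above background on 4 and 2 of 8 spots in the mutant and on 1 of 8 in the wild type at each pH, and slr0644 did not pass the test (0.02 and 0.08).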
